A study of Homo sapiens with 4 samples.

How the data were processed

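Gene expression was measured by RNA sequencing in human SEM cells, an established B-cell precursor acute lymphoblastic leukaemia line that carries the KMT2A-AFF1 (MLL-AF4) fusion, after the cells had been transplanted into immunodeficient mice. There were 4 libraries, 2 of cells retrieved from brain and 2 of cells retrieved from spleen. Per the labels, RNA of 5 mice was combined in each library, leukaemic cells were enriched on a Ficoll gradient and their purity was determined by flow cytometry. The purities themselves are not given in the sources used here. RNA was isolated with TRIzol, treated with DNase and converted to stranded, poly(A)-selected libraries, per the labels' protocols.

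Per the submitters' processing notes, bcl2fastq 1.8.4, cutadapt 1.5, kallisto 0.42.4 and DESeq2 were used, with the genome builds GRCh38 and GRCm38. The settings, the strand option and the annotation release are not given in the sources used here. The transcript files deposited by the authors hold an estimated count for each of 199596 human and 104229 mouse transcripts in every library, and the same files give TPM, a level per transcript scaled by length over both species together. The gene table deposited by the authors holds estimated counts summed over transcripts of 65217 human genes and rounded to whole numbers, without normalisation. This was checked against the transcript files: with transcripts assigned to genes by GENCODE release 44, between 77.2% and 78.5% of genes over 50 counts equalled the transcript sums within 1 count. A further table deposited by the authors holds regularised log values on a log2 scale. The count table and the log2 table each hold 1 more column of values whose name matches no sample of the series. Both of these columns, 2 in all, were not used here, and the log2 values had been computed together with one of them.

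The count test was designed for counts, and the deposited values are rounded estimated counts, to which it was applied as planned. The total of the gene counts was 36913437 and 33055465 in the brain libraries and 32972842 and 26266136 in the spleen libraries, so that 3 counts, the limit that a count of 0 allows, correspond to between 0.0813 and 0.114 CPM (counts scaled to a library total of 1e6). Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Gene symbols, positions and classes were taken by identifier from GENCODE release 44 on GRCh38, in which 56322 identifiers (86.4%) were found. These held at least 99.7% of the counts of every library. Mouse transcripts were summed and not assigned to genes.

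Brain was compared with spleen by edgeR's quasi-likelihood test (edgeR 4.0.16, robust fit, R 4.3.3) on the rounded counts with TMM factors. Genes were filtered by filterByExpr with the groups, which left 17075. P-values were adjusted by the Benjamini-Hochberg method, and genes under 0.05 were called. Fold changes are log2 of brain over spleen with the standard error implied by the test statistic. Levels are CPM with TMM factors, given as mean ± SD over the 2 libraries of a group. The 2 libraries of a group differed by more than sampling noise, with a mean chi-square per gene of 9.37 in brain and 67.3 in spleen where sampling alone gives about 1. They were therefore not repeat samplings of the same library. This does not show independent biological replication, and each was counted as a replicate on the word of the labels. Per the labels the replicate number marks an independent occasion of the whole experiment, and it was therefore taken to pair a brain with a spleen library. Over the tested genes, the deviations of same-numbered libraries from their group means had a Pearson correlation of 0.0269 and a Spearman correlation of -0.0149, across genes, which are not independent replicates. The fit with the replicate number as a block was an alternative, and its value stands beside a result of the main test where it changes the call or moves a count by over 1.5 times. A smaller p with the block was not read as stronger support, since the correlations above are near 0.

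The 44 gene lists, the rule for named genes and the main tests were fixed before the data were examined. Of the 44 lists, 40 had at least 3 measured members and were tested by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and the p-values were adjusted over the 40. Members of a list were called by the test over all genes, and also by a test adjusted over the list alone. The rule named the 10 genes of largest fold change in each direction that had a symbol, passed the threshold, had no overlap between groups and reached a mean of 5 CPM in the higher group. It also named up to 4 called members of each list (or 2 members of highest level where none was called) and 14 genes chosen in advance. With 2 libraries against 2, an exact permutation test cannot give a p under 0.333, the share of the 6 splits that any result reaches.

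The scripts were tested on simulated data drawn for the same 17075 genes and library sizes, with 200 genes changed. For brain against spleen, edgeR recovered 8.36% of genes changed by a fold of 1.5, 58.2% at a fold of 2 and 100% at a fold of 4, and 4.33% of its calls were false when the spread followed the trend with expression. When each simulated gene kept its own estimated spread, 16.1% of the calls were false for the main test and 21.9% with the replicate block. Of 8 simulated lists shifted by a fold of 2 all 8 were called, and of 32 unshifted lists 0 were called. Simulated genes were drawn independently and their lists at random, so this does not test lists whose members vary together. In the real lists the estimated correlation between members reached 0.977 (mitochondrially encoded genes).

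The alternatives were the replicate block, other scaling factors (RLE, upper quartile), no filter or a stricter filter on low counts, DESeq2 1.42.0 with and without the block, limma-voom, each library left out in turn, gene sums of the transcript files, limma on the deposited log2 values, a test against a fold of 1.5, and for lists camera with an estimated correlation and fry. Alternatives chosen after seeing the data were the removal of each library's trend with GC content and transcript length (mgcv 1.9.3), with and without the block, thinning to the smallest total, protein-coding genes alone, edgeR's bias-adjusted variant, library sizes that include the mouse transcripts (with TMM factors), and camera with both the estimated correlation and the block. Shares of mouse counts were compared by an exact two-sided permutation test (SciPy 1.17.1).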

Results

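The series compared SEM cells, a human KMT2A-AFF1 leukaemia line, that had settled in the central nervous system of transplanted mice with cells of the same line from the spleen. There were 2 libraries of cells from brain and 2 of cells from spleen, and RNA of 5 mice was pooled in each. The deposited gene counts summed to 36913437 and 33055465 in brain and to 32972842 and 26266136 in spleen. On log2 CPM the brain libraries correlated at 0.991 across genes and the spleen libraries at 0.980, and brain with spleen libraries at 0.965 to 0.979. Spleen replicate 2 stood apart by base composition: its median deviation from the 4-library mean was -0.37 (log2) in the fifth of genes lowest in GC content, against 0.11 to 0.17 in the other libraries. A trend with transcript length followed the site. In the fifth of genes with the longest transcripts the deviation was 0.12 and 0.17 in brain and -0.01 and -0.23 in spleen. In the fifth with the shortest it was -0.06 and -0.04 in brain and 0.06 and 0.02 in spleen.

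The question was which genes and pathways differed between leukaemic cells at the 2 sites. In cells from brain, 16 of 20 hypoxia response genes, 10 of 20 cholesterol synthesis genes, 6 of 20 glycolysis genes, 3 of 13 fatty acid synthesis genes and 5 of 10 MHC class II genes rose, and 2 of 13 genes encoded by the mitochondrial genome fell. Each of these lists passed as a set with a preset correlation, and none passed with an estimated correlation (adjusted p = 0.219 to 0.434 with an estimated correlation). The estimated correlation was 0.00567 for fatty acid synthesis, 0.0166 for cholesterol and 0.0635 for hypoxia. It was 0.482 for glycolysis, 0.955 for MHC class II and 0.977 for the mitochondrial list. The fatty acid value lies under the preset 0.01, so correlation within that list did not end its call. The estimated setting also takes its p from a distribution set by the number of libraries, and with 4 it has little power. The sterol uptake list had an estimated correlation of -0.0816. Its unadjusted camera p was 2.27e-10 with the preset correlation and 0.0222 with the estimated one. Failure with an estimated correlation therefore tells little for or against a list, here and below. Of 17075 genes tested, 345 were called, 279 higher and 66 lower in brain (edgeR, adjusted p under 0.05). At an unadjusted p under 0.05 the numbers were 1828 higher and 1697 lower, and the median log2 fold change of all genes was 0.04. Protein-coding genes made up 242 of the genes higher in brain and 31 of those lower, where 24 were long non-coding RNAs. With the replicate number as a block, 1278 genes were higher and 575 lower, and all 345 were among them. The added calls do not show that pairing removed variation, since same-numbered libraries deviated almost independently (Pearson correlation 0.0269). For SQLE the standard error rose from 0.157 to 0.205 with the block, yet edgeR's p fell from 1.43e-05 to 3.01e-13. The standard error of HLA-DRA shrank, from 0.232 to 0.202. The split depended on the processing, with 533 higher and 408 lower by DESeq2, 417 higher and 291 lower after removal of the GC and length trend, and 1152 higher and 1219 lower with that removal and the block. Without brain replicate 2 the total was 551, without spleen replicate 1 it was 6807 (3392 higher, 3415 lower), and without spleen replicate 2 it was 3128, where a lone library is assumed to vary like the other group.

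The named genes with the largest rise in brain included several of glucose and energy metabolism. SLC16A3, a lactate exporter (chromosome 17, 82217934 to 82261129, GRCh38), had 26.0 ± 1.94 CPM in brain and 0.758 ± 0.215 in spleen (SD, n = 2 in each group here and below), a log2 fold change of 5.12 ± 0.26 (SE, adjusted p = 0.00024). AK4, a mitochondrial adenylate kinase, rose by 4.61 ± 0.22 (adjusted p = 0.000177), ENO2, an enolase, by 4.35 ± 0.32 and PFKFB4, a regulator of glycolytic flux, by 4.14 ± 0.27. The transcription factor BHLHE40 rose by 4.08 ± 0.19, the surface protein gene LRRC32 by 4.77 ± 0.34, TBC1D30 by 4.59 ± 0.27 and SPRY1, an inhibitor of receptor tyrosine kinase signalling, by 4.03 ± 0.34. RGS1, a regulator of G protein signalling in lymphocytes, had 1095 counts in brain and 2 in spleen, a ratio of CPM of 464 (95% exact interval 128 to 3832, counting error only). H3P6 had 1213 counts in brain and 0 in spleen, at least 331-fold higher against a floor of 3 counts over the group. It is a processed pseudogene of a histone gene and its count is uncertain; its call ended by DESeq2 with the block (adjusted p = 0.102).

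Among the named genes that fell in brain, CD34, a surface marker of haematopoietic progenitors, had 120 ± 21.7 CPM in brain and 308 ± 40.1 in spleen and fell by 1.37 on the log2 scale (SE 0.18, adjusted p = 0.0126). FST, which encodes the activin-binding protein follistatin, fell by 1.73 (SE 0.22), SUSD4 by 1.34 (SE 0.24), PTGDR2, a prostaglandin receptor gene, by 1.29 (SE 0.20) and KIF25 by 1.78 (SE 0.30). Of the others, CERS6-AS1 (log2 fold change -4.55) and TUBA1B-AS1 (-3.59) are antisense to protein-coding genes, ZACN (-2.77) overlaps its neighbours, ATP6V1G2-DDX39B (-1.37) is a read-through of 2 genes and SULT1A4 (-1.40) has a near-identical copy, so their counts are uncertain. The call of TUBA1B-AS1 ended without spleen replicate 1 (adjusted p = 0.143) and without spleen replicate 2 (adjusted p = 0.229), SUSD4 ended without brain replicate 2 (adjusted p = 0.114) ATP6V1G2-DDX39B without brain replicate 1 (adjusted p = 0.0740), and CERS6-AS1 (adjusted p = 0.0595) and KIF25 (log2 fold change -1.29, adjusted p = 0.119) with gene sums of the transcript files. With the stricter filter the calls of KIF25 (adjusted p = 0.0539), CERS6-AS1 (adjusted p = 0.0548), SUSD4 (adjusted p = 0.0529) and ATP6V1G2-DDX39B (adjusted p = 0.0576) ended as well.

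**Figure D1:**
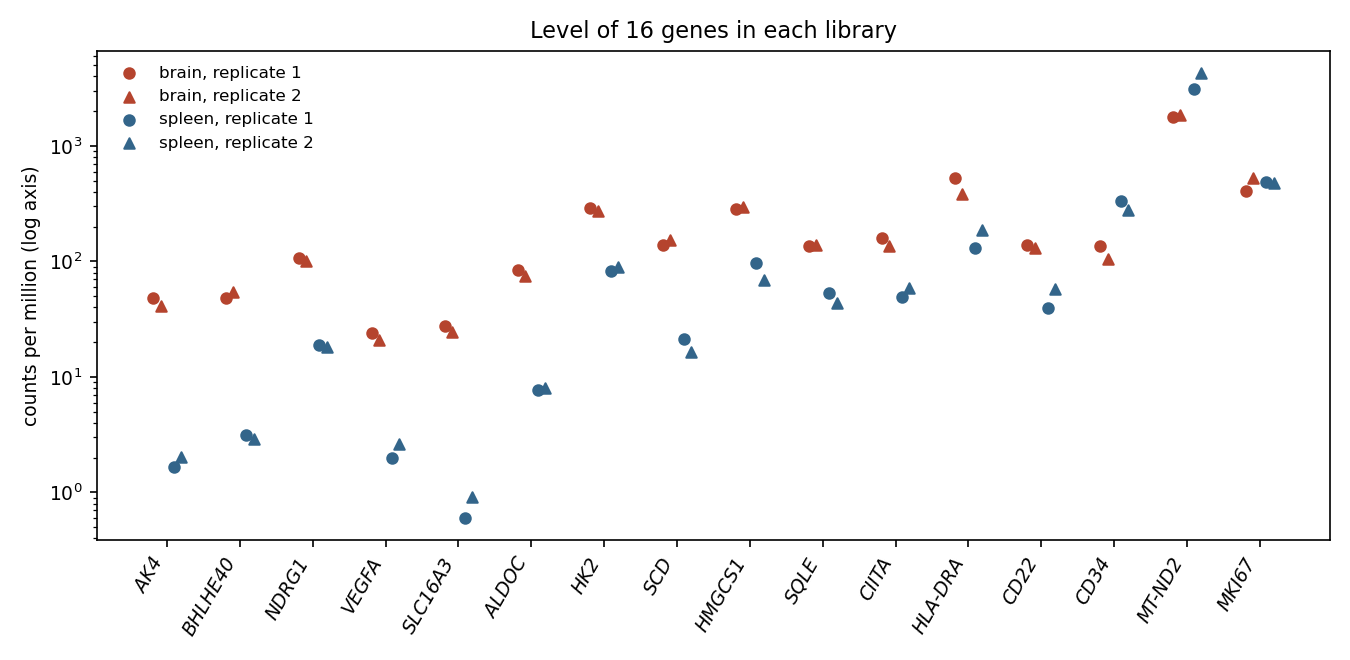
Level of 16 named genes in each library, in CPM on a log axis, with brain in red, spleen in blue, circles for replicate 1 and triangles for replicate 2. For SCD the brain libraries lie near 147 and the spleen libraries near 18.9 CPM, while MKI67 lies near 471 in brain and 481 in spleen.

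The next question concerned gene lists fixed in advance. Of 40 lists, 22 passed 0.05 by camera with a preset correlation, 13 higher and 9 lower in brain. With an estimated correlation, a setting of little power with 4 libraries, 0 of the 40 passed. The smallest adjusted p was 0.219, while 4 lists had an unadjusted p under 0.05. By fry 5 were called, all higher in brain, and 0 with the block.

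Hypoxia response genes, which are induced when oxygen is scarce, showed the largest shift. Of 20 measured members 16 rose, 0 fell and 4 did not pass, and 19 rose adjusted over the list alone. All 20 had a positive log2 fold change, with a median of 1.60. VEGFA, the angiogenic growth factor (chromosome 6, 43770184 to 43786487), had 22.4 ± 2.06 CPM in brain and 2.33 ± 0.460 in spleen, a log2 fold change of 3.27 ± 0.23 (adjusted p = 0.000938). NDRG1, a stress-response gene, rose from 18.5 ± 0.685 to 105 ± 4.91 CPM. The list passed by camera (adjusted p = 1.35e-64) and by fry (adjusted p = 0.0137; with the block 0.118), with adjusted p = 0.219 with an estimated correlation. Share of mouse counts, an index of other cells, was lower in brain (1.84% ± 0.560 against 5.32% ± 1.42).

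Glycolysis genes rose in part. Of 20 members 6 rose and 14 did not pass, and 7 rose adjusted over the list alone. The members that rose were led by SLC16A3 and ENO2, by ALDOC, an aldolase (79.8 ± 7.04 CPM in brain, 7.86 ± 0.305 in spleen), and by HK2, a hexokinase that starts glucose breakdown (281 ± 10.9 and 86.5 ± 5.45 CPM, log2 fold change 1.70 ± 0.14). The median of the list was 0.22 and its mean 0.96, and the median was 0.04 without spleen replicate 1 and 0.42 without spleen replicate 2. Members summed to 13451 and 12432 CPM in the brain libraries and to 10175 and 12509 CPM in the spleen libraries. It passed by camera (adjusted p = 1.39e-14) and had adjusted p = 0.434 with an estimated correlation.

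Of 20 cholesterol biosynthesis enzymes 10 rose in brain, 0 fell and 10 did not pass, and 16 rose adjusted over the list alone; the study's own report, as remembered, named this pathway, so the list is not independent evidence of its direction. HMGCS1, which makes HMG-CoA from acetyl units, rose from 83.0 ± 20.5 to 291 ± 7.68 CPM (log2 fold change 1.81 ± 0.19, adjusted p = 0.00569). SQLE, which oxidises squalene, rose by 1.49 ± 0.16. MSMO1 and CYP51A1, enzymes of the later steps, rose by 1.36 ± 0.15 and 1.31 ± 0.14. The median of the list was 0.90 (camera, adjusted p = 3.62e-16; fry, adjusted p = 0.0137, with the block 0.110; adjusted p = 0.219 with an estimated correlation).

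Of 9 genes of sterol uptake and of SREBP, the transcription factor family that responds to low sterol, 3 rose and 6 did not pass, 7 rose adjusted over the list alone and 6 rose with the block. They included INSIG1, a sterol-responsive regulator of SREBP (log2 fold change 1.78 ± 0.17, adjusted p = 0.00358), and SREBF2 (0.91 ± 0.13, adjusted p = 0.021). The call of SREBF2 ended without brain replicate 1 (adjusted p = 0.0518) and without brain replicate 2 (adjusted p = 0.0774). SREBF1 had a log2 fold change of 0.75 ± 0.17 that did not pass (adjusted p = 0.0722) and passed with the block (adjusted p = 0.00409). The median of the list was 0.75 (camera, adjusted p = 1.3e-09; fry, adjusted p = 0.0137, with the block 0.110; adjusted p = 0.222 with an estimated correlation).

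Of 13 genes of fatty acid synthesis and desaturation 3 rose and 10 did not pass, 4 rose adjusted over the list alone and 5 rose with the block. SCD, the desaturase that makes monounsaturated fatty acids (chromosome 10, 100347233 to 100364826), had 147 ± 9.16 CPM in brain and 18.9 ± 3.24 in spleen, a log2 fold change of 2.96 ± 0.18 (adjusted p = 0.00043). FADS1, a desaturase of polyunsaturated fatty acids, rose by 1.06 ± 0.14 and FASN, fatty acid synthase, by 0.75 ± 0.14 (adjusted p = 0.045). The call of FASN ended without brain replicate 1 (adjusted p = 0.198) and without brain replicate 2 (adjusted p = 0.234), with RLE factors (adjusted p = 0.0624) and by DESeq2 with the block (adjusted p = 0.0603), among others. The median of the list was 0.23 (camera, adjusted p = 0.000442; fry, adjusted p = 0.017, with the block 0.163; adjusted p = 0.434 with an estimated correlation), and it was 0.11 after removal of the GC and length trend. Among 8 LXR targets and sterol efflux genes 1 rose, MYLIP, which encodes a ubiquitin ligase (log2 fold change 1.56 ± 0.16), 2 rose adjusted over the list alone and 2 with the block. That list did not pass (adjusted p = 0.187; without spleen replicate 2, 0.0257), with a median of -0.05 and a mean of 0.31.

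Of 13 genes encoded by the mitochondrial genome 2 fell in brain, 0 rose and 11 did not pass, 12 fell adjusted over the list alone and 10 fell with the block. MT-ND2, a subunit of respiratory complex I, had 1811 ± 41.6 CPM in brain and 3687 ± 847 in spleen and fell by 1.03 on the log2 scale (SE 0.18, adjusted p = 0.0378). MT-ATP8, whose reading frame overlaps that of MT-ATP6, fell by 0.99 (SE 0.17). The median of the list was -0.99 (camera, adjusted p = 4.46e-13; adjusted p = 0.434 with an estimated correlation). The list took 2.54% and 2.64% of the counts in the brain libraries, 3.74% in spleen replicate 1 and 5.48% in spleen replicate 2, and the median was -0.63 without the latter. The share of mouse counts was also higher in spleen (5.32% ± 1.42 against 1.84% ± 0.560). The MT-ND2 call ended with the stricter filter (adjusted p = 0.0554), among protein-coding genes alone (adjusted p = 0.0531) and without brain replicate 1. The MT-ATP8 call ended without brain replicate 2. After removal of the GC and length trend neither passed, with folds of like size (MT-ATP8 -1.05, adjusted p = 0.122, and MT-ND2 -1.01, adjusted p = 0.0504).

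Nuclear genes of oxidative phosphorylation had a median log2 fold change of -0.40 and 0 of 32 positive values. Of the 32 members 0 passed, 13 fell adjusted over the list alone and 6 fell with the block. ATP5F1B and ATP5F1A, subunits of ATP synthase, had log2 fold changes of -0.26 ± 0.15 and -0.26 ± 0.14. The list passed by camera (adjusted p = 6.65e-08), with adjusted p = 0.437 with an estimated correlation. Fatty acid oxidation genes, of which 0 of 17 passed, 2 fell adjusted over the list alone and 2 fell with the block, had a median of -0.29 (camera, adjusted p = 0.00182; adjusted p = 0.434 with an estimated correlation). HADHA had a log2 fold change of 0.08 ± 0.14 and ETFA one of -0.54 ± 0.13.

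**Figure D2:**
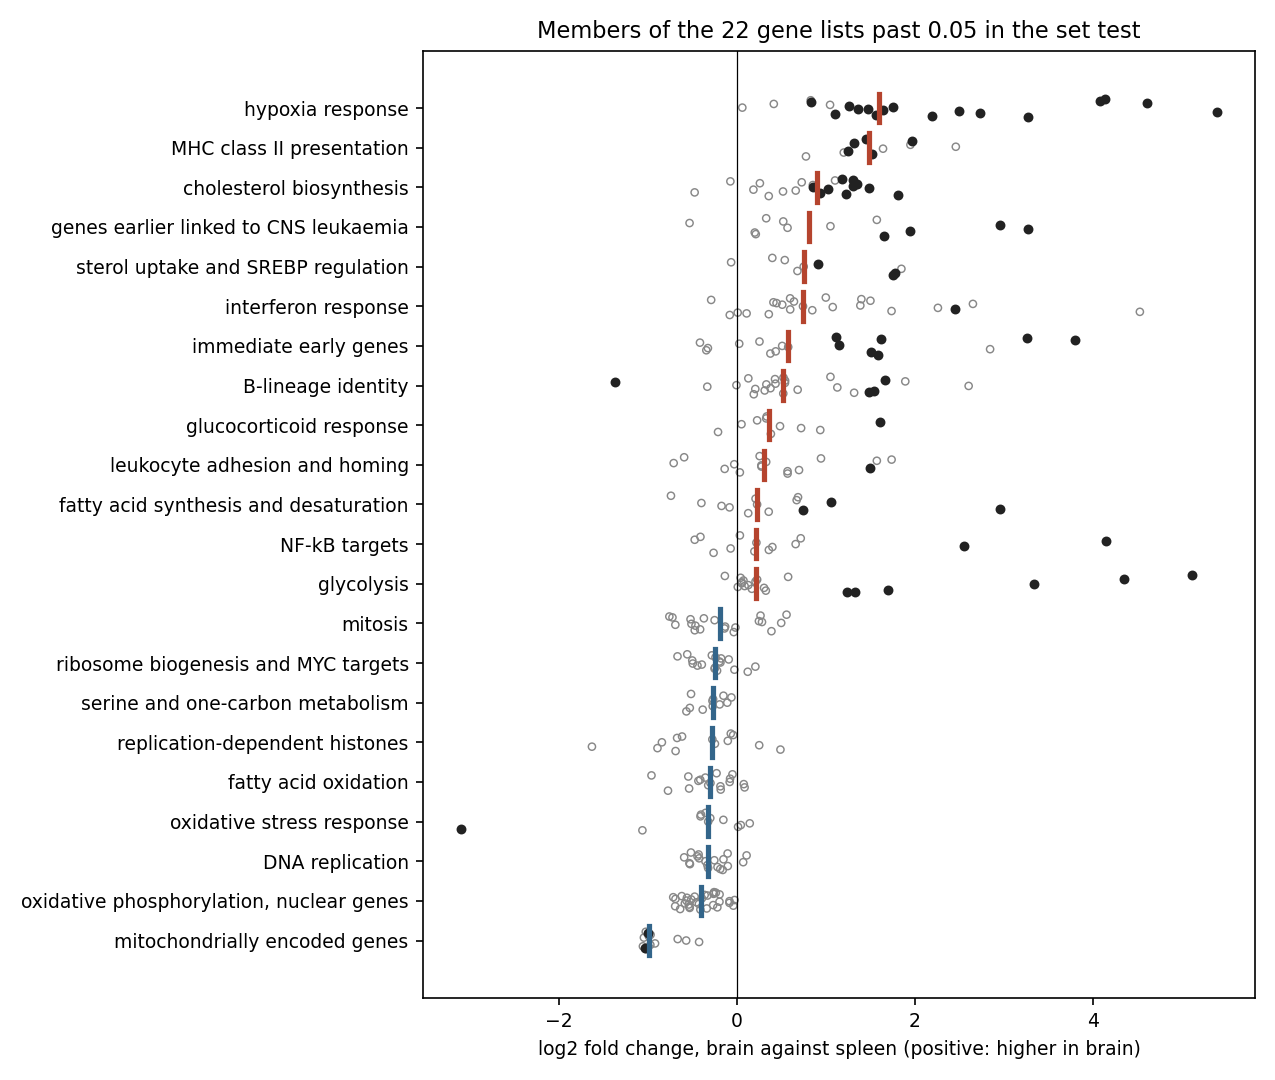
Log2 fold change of brain against spleen (x axis) for the measured members of the 22 lists past 0.05 by camera with a preset correlation, with filled points for called genes, open points for the others and a bar at the median. Medians run from -0.99 for the mitochondrially encoded genes to 1.60 for the hypoxia response.

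Of 10 MHC class II genes, which present peptides to helper T cells, 5 rose in brain and 5 did not pass, and 10 rose adjusted over the list alone and with the block. CIITA, the master activator of the class (chromosome 16, 10866222 to 10943021), had 147 ± 16.8 CPM in brain and 53.7 ± 6.82 in spleen, a log2 fold change of 1.45 ± 0.16 (adjusted p = 0.00747). HLA-DRA rose by 1.52 ± 0.23, HLA-DPA1 by 1.25 ± 0.19 and HLA-DMB by 1.97 ± 0.26. Counts of this polymorphic family are uncertain. HLA-DPA1 did not pass after removal of the GC and length trend (adjusted p = 0.0526), nor did HLA-DRA with the stricter filter (adjusted p = 0.0503). Over the list the median was 1.49 (camera, adjusted p = 9.67e-16; adjusted p = 0.434 with an estimated correlation). MHC class I genes did not pass as a list (0 of 12 members called, 1 higher with the block, median -0.06, mean 0.01, adjusted p = 0.856), with B2M at 0.14 ± 0.14 and HLA-B at -0.14 ± 0.18.

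B-lineage identity genes had a positive log2 fold change in 21 of 24 members. Of 24 members 3 rose and 1 fell, 11 rose and 1 fell adjusted over the list alone, and 8 rose and 1 fell with the block. CD22, a B-cell lectin, rose from 48.6 ± 12.4 to 136 ± 5.44 CPM (log2 fold change 1.48 ± 0.19, adjusted p = 0.0147), CD24 rose by 1.67 ± 0.28 and MS4A1, which encodes CD20, by 1.54 ± 0.30, while CD34 fell. The MS4A1 call ended without brain replicate 1 (adjusted p = 0.136) and by DESeq2 with the block (adjusted p = 0.178), among others. Over the 24 members the median was 0.53 (camera, adjusted p = 1.7e-06; adjusted p = 0.434 with an estimated correlation), and it was 0.29 without spleen replicate 1. Targets and cofactors of KMT2A-rearranged leukaemia did not pass (0 of 18 members called, 1 fell adjusted over the list alone and 1 with the block, median 0.13, adjusted p = 0.833), with HOXA9 at -0.24 ± 0.15, FLT3 at 0.36 ± 0.17 and MEF2C at 0.28 ± 0.16.

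Genes that earlier work had linked to central nervous system leukaemia rose in part. Of 12 members 4 rose and 8 did not pass, 6 rose adjusted over the list alone and 7 rose with the block. They were VEGFA, SCD, ZAP70, a kinase of antigen receptor signalling (41.5 ± 4.03 CPM in brain and 13.2 ± 3.22 in spleen, log2 fold change 1.66 ± 0.21, adjusted p = 0.012) and SPP1, which encodes osteopontin (1.94 ± 0.36, adjusted p = 0.0408). The SPP1 call ended with the stricter filter (adjusted p = 0.0591), among protein-coding genes alone (adjusted p = 0.0577) and without brain replicate 1. IL15 (0.22 ± 0.30) and MERTK (0.20 ± 0.41) did not pass; their levels were at most 2.51 CPM. Across the 12 the median was 0.81 (camera, adjusted p = 1.85e-12; fry, adjusted p = 0.0223, with the block 0.118; adjusted p = 0.219 with an estimated correlation), and it was 1.32 with the stricter filter.

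Genes of cell division had small negative medians and 0 called members. DNA replication genes had a median of -0.32 over 19 members, 3 of which fell adjusted over the list alone and 1 with the block (camera, adjusted p = 0.0007; adjusted p = 0.464 with an estimated correlation), with MCM7 at -0.33 ± 0.14 and UHRF1 at -0.10 ± 0.16. Mitosis genes had a median of -0.19 over 20 members, 8 of which fell adjusted over the list alone and 3 with the block (camera, adjusted p = 0.00984; adjusted p = 0.434 with an estimated correlation). That call did not hold with the block (adjusted p = 0.105), nor without brain replicate 1 (adjusted p = 0.164), brain replicate 2 (adjusted p = 0.0570) or spleen replicate 1 (adjusted p = 0.453, with the opposite direction). MKI67, a marker of cycling cells, had 471 ± 86.7 CPM in brain and 481 ± 3.96 in spleen, and TOP2A 739 ± 33.0 and 564 ± 255.

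The last comparison asked how many counts came from mouse cells. Mouse transcripts took 2.24% and 1.45% of the estimated counts in the brain libraries and 4.31% and 6.32% in the spleen libraries. The means were 1.84% ± 0.560 in brain and 5.32% ± 1.42 in spleen (SD, n = 2 each), a difference of 3.47 percentage points. The exact two-sided permutation p was 0.333, the smallest this design allows. Of human markers of other cells, 4 lists had under 3 measured members and were not tested. Erythroid genes had 22 and 31 counts in the brain libraries and 32 and 13 in the spleen libraries, neutrophil and myeloid genes 80, 85, 156 and 142, platelet genes 77, 43, 69 and 35, and choroid plexus genes 1, 3, 0 and 0, of totals of 26266136 to 36913437. MPO, a neutrophil granule gene, had a log2 fold change of -1.19 ± 0.27 that did not pass (adjusted p = 0.0704; with the block 0.00408).

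**Figure D3:**
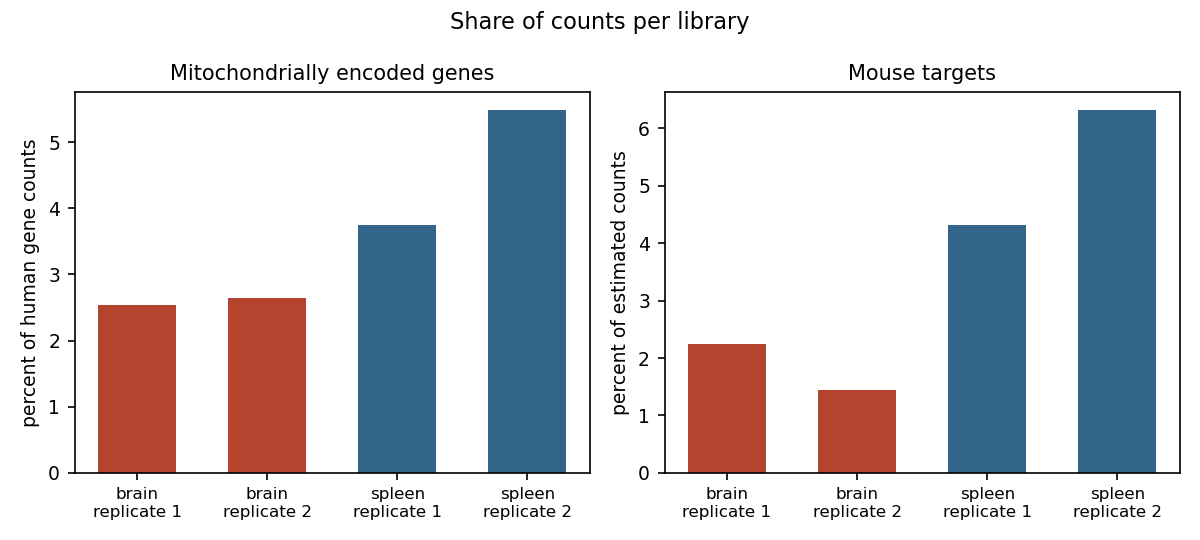
Percent of human gene counts on 13 mitochondrially encoded genes (left) and percent of estimated counts on mouse transcripts (right) in each library, with brain in red and spleen in blue and bars from 0. Both shares lie higher in the spleen libraries, with 3.74% and 5.48% on the left and 4.31% and 6.32% on the right.

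Lists of the other cell types with at least 3 measured members did not pass. Adjusted p was 0.115 for neurons (5 members, median 1.00), 0.0571 for astrocytes (4 members, median -0.51, mean 0.28), 0.903 for oligodendrocytes (3 members, median -0.30), 0.553 for fibroblasts and leptomeninges (3 members, median 0.53), 0.242 for endothelial and mural cells (7 members, median -0.16), 0.212 for macrophages and microglia (8 members, median -0.25) and 0.101 for T and NK cells (3 members, median -0.49). The only called member over these lists was ALDOC, which is also a glycolysis gene. With the block 1 member was called higher in each of the neuron, astrocyte, fibroblast and macrophage lists, and 1 lower in each of the astrocyte, macrophage, T and NK and endothelial lists. SYT1, a synaptic gene, had 42.8 ± 7.56 CPM in brain and 20.3 ± 5.70 in spleen and did not pass (adjusted p = 0.0712; with the block 7.11e-05), but passed by DESeq2 (adjusted p = 0.00431), among others. Myelin gene MBP had 124 ± 10.7 and 91.0 ± 2.27 CPM, and GZMA, a cytotoxic granule gene, 16.1 ± 2.49 and 37.0 ± 14.4 CPM (adjusted p = 0.108; with the block 2.49e-05). COL1A1, a collagen gene, had 1.71 ± 0.302 CPM in brain and 0.598 ± 0.330 in spleen (adjusted p = 0.118; with the block 0.00667). By camera the astrocyte list passed, higher in brain, with a stricter filter (adjusted p = 0.00468) and after thinning (adjusted p = 0.00439). It also passed after removal of the GC and length trend (adjusted p = 0.00961, with the block 0.0444), and in other settings, among them those without either spleen library. In the main test 1 of its 4 members had a positive log2 fold change, ALDOC at 3.34, so that direction rests on a glycolysis gene. The median of the list was -0.18 without spleen replicate 1 and -0.78 without spleen replicate 2. T and NK genes passed without spleen replicate 2 (adjusted p = 0.00671) and with the stricter filter (adjusted p = 0.0350), and macrophage genes without brain replicate 1 (adjusted p = 0.0340), lower in brain.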

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

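The tests of the explanations in this part were chosen after the result they bear on had been seen, except the one on the largest mouse transcripts. The leave-outs and the list tests among them had been fixed in advance for other use.

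The hypoxia response and cholesterol synthesis lists did not pass with an estimated correlation (adjusted p = 0.219, and 0.597 with the block). With 4 libraries that setting has little power, least with the block, so these values tell little for or against the lists. Of the hypoxia response genes 16 of 20 and of the cholesterol synthesis genes 10 of 20 were higher in brain. A GC and length trend does not account for this, since with the trend removed and the replicate block kept the median of the hypoxia list was 1.52 (adjusted p = 6.41e-60; with the block alone 1.62, 4.93e-52) and that of the cholesterol list 0.82 (adjusted p = 1.19e-16; with the block alone 0.90, 5.72e-13). Reads of mouse cells at the brain counted on human genes would raise other-cell markers too. The 57 markers silent in spleen gained 2.12 CPM, 0.209% of the 1016 CPM that the hypoxia list gained. Of 73 markers the 33 that gained, SYT1 and MBP most, gained 77.0 CPM (7.58%), and the 73 together had a net difference of -30.9 CPM. ALDOC, an astrocyte marker that is also a glycolysis gene, was left out of the 73. It had 79.8 CPM in brain and 7.86 in spleen, a larger gain than that of SYT1 or MBP. Counting it would raise the gain and the net difference, so these values do not settle the question. Cell retrieval and handling differ between the organs and cannot be told apart from the group: the immediate early list had a median of 0.58 (adjusted p = 6.82e-08; adjusted p = 0.434 with an estimated correlation) and the heat shock list one of 0.03 (adjusted p = 0.743). The hypothesis that the brain site itself is low in oxygen and sterol could not be tested with these libraries.

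Of the mitochondrially encoded genes 2 of 13 were lower in brain and of the nuclear oxidative phosphorylation genes 0 of 32 passed. Neither list passed with an estimated correlation (adjusted p = 0.434 and adjusted p = 0.437, and 0.597 for both with the block). With 4 libraries that setting has little power, least with the block, so these values tell little for or against the lists. With the GC and length trend removed and the block kept, the medians were -0.90 (adjusted p = 3.14e-11; with the block alone -0.94, 1.10e-14) and -0.40 (adjusted p = 1.68e-06; with the block alone -0.39, 3.90e-07), which argues against that trend. Without spleen replicate 2 they were -0.63 (adjusted p = 1.77e-17) and -0.27 (adjusted p = 6.19e-08), which argues against that library as the sole source. Mouse reads on human mitochondrial genes might add to the spleen share, and the test cannot tell: the library with more mouse counts differed from its partner by -0.107 percentage points in brain and by 1.74 in spleen, and 25.6% and 42.9% of the mouse counts of the spleen libraries would be needed. A lower use of respiration by cells in brain is a hypothesis that RNA levels alone do not test.

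Mouse transcripts took 2.24% and 1.45% of the estimated counts in the brain libraries and 4.31% and 6.32% in the spleen libraries, above the 7.94e-06% to 1.07e-05% that a count of 0 allows. Smaller human totals in spleen do not account for the difference, since the mean mouse count itself was 2.45 times as high there. Human reads counted on mouse transcripts at a fixed rate would give equal ratios of mouse to human counts, and the highest ratio was 4.59 times the lowest. The 10 mouse transcripts with the most counts in spleen held 13.4% of the mouse counts there, so a few transcripts do not account for it. The same 10, chosen on spleen, held 7.18% in brain. More mouse cells left after purification of spleen is the hypothesis that stays open, and their kind was not tested for want of a mouse annotation.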

How the results depend on the processing

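The number of called genes depended strongly on the processing, and the larger number higher than lower in brain did not hold in every setting. From 345 called genes (279 higher, 66 lower), the total was 1853 (1278 higher, 575 lower) with the replicate block, 2123 (1269 and 854) without a filter, 210 (180 and 30) with a stricter filter and 941 (533 and 408) by DESeq2. The lower count was 111 by DESeq2 with the block and 108 by limma on the deposited log2 values. Against a fold of 1.5 there were 81 (69 and 12), and among protein-coding genes alone 201 (184 and 17). With the GC and length trend removed the total was 708 with 291 lower, and with the block as well 2371 (1152 higher and 1219 lower), where more genes were lower than higher. Leaving out a library gave totals from 404 to 6807, 297 to 3392 higher and 107 to 3415 lower. A leave-out leaves 1 library in a group, whose spread is then taken from the other group. Of the 22 lists, 0 were called (0 higher, 0 lower) by camera with an estimated correlation, 0 (0 and 0) with that correlation and the block, 5 (5 and 0) by fry and 0 (0 and 0) by fry with the block. With 4 libraries the settings with an estimated correlation have little power, so their 0 calls tell little about the lists. The cholesterol list lost its call in 3 settings with its median kept: 0.90 by camera with the estimated correlation (adjusted p = 0.219), 0.90 with the block as well (adjusted p = 0.597) and 0.90 by fry with the block (adjusted p = 0.110). By limma on the deposited log2 values, which are shrunken, its median was 0.53 (adjusted p = 4.72e-10). Without spleen replicate 2 the mitosis list had a median of -0.32, and without spleen replicate 1 one of -0.16 with the set test turned (adjusted p = 0.453). Cytosolic ribosomal proteins had medians of -0.13 (adjusted p = 0.0348) and 0.16 (adjusted p = 0.0157) without spleen replicate 1 and 2. Among named genes, over all settings, 1102 calls were kept and 88 lost, and of 57 called genes all 57 kept their call with the block, 51 of 55 by DESeq2 with the block, 42 of 56 with the stricter filter and 31 against a fold of 1.5. The block made more calls in all (1853 against 345), so keeping the 57 there is a weak check. The difference in mouse share was 2.47 to 4.47 percentage points when a library was left out, 4.21 by TPM and 3.46 over transcripts with at least 10 counts. With library sizes that include mouse transcripts, taken from the transcript files, 340 genes were called (274 higher, 66 lower) and 22 lists. The TMM factors rescale the libraries on the human genes whatever total is given, so this setting was no check on mouse reads.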

Other observations

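Interferon response genes had a median log2 fold change of 0.75, with 21 of 23 positive. Of the 23 members 1 rose, 17 rose adjusted over the list alone and 13 rose with the block. IFITM1, an antiviral membrane protein gene, had 12.1 ± 3.33 CPM in brain and 2.23 ± 0.320 in spleen (log2 fold change 2.45 ± 0.28, adjusted p = 0.0075). The list passed by camera (adjusted p = 5.74e-09), with adjusted p = 0.434 with an estimated correlation. Of 17 immediate early genes, which respond within minutes to stimuli, 7 rose and 9 rose adjusted over the list alone (median 0.58, camera adjusted p = 6.82e-08; adjusted p = 0.434 with an estimated correlation), and the median was 1.14 without brain replicate 2. Those that rose included the nuclear receptor genes NR4A1 (3.80 ± 0.36), NR4A2 (1.63 ± 0.25) and NR4A3 (3.26 ± 0.54), and FOS (1.59 ± 0.26), whose call ended without spleen replicate 1 (adjusted p = 0.329) or 2 (adjusted p = 0.380). Of 13 NF-kB targets 2 rose, 4 rose adjusted over the list alone and 4 rose with the block (median 0.22, camera adjusted p = 0.0221; adjusted p = 0.434 with an estimated correlation), and the list did not pass with the block (adjusted p = 0.0663), without brain replicate 2 (adjusted p = 0.0636) or spleen replicate 1 (adjusted p = 0.547), with the stricter filter (adjusted p = 0.136), by limma-voom (adjusted p = 0.0572) or on the deposited log2 values (adjusted p = 0.0579). BIRC3, an inhibitor of apoptosis, rose by 2.55 ± 0.40 (by DESeq2 with the block, adjusted p = 0.0595), and CXCL8, a chemokine gene, had 69 counts in brain and 3 in spleen (ratio of CPM 19.5, 95% exact interval 6.39 to 96.7). The CXCL8 call ended after thinning (adjusted p = 0.0535) and among protein-coding genes alone (adjusted p = 0.0531). SGK1, a kinase, rose by 1.62 ± 0.29, a call that ended with the stricter filter (adjusted p = 0.0539). It was 1 of 10 glucocorticoid response genes (3 rose adjusted over the list alone, 2 with the block, median 0.36, camera adjusted p = 0.00783, adjusted p = 0.434 with an estimated correlation). Without spleen replicate 1 that list did not pass (median 0.17, adjusted p = 0.263). ITGB2, an integrin chain, rose from 10.8 ± 0.285 to 30.7 ± 11.2 CPM (adjusted p = 0.0437), 1 of 16 adhesion and homing genes (3 rose and 1 fell adjusted over the list alone, 6 rose and 1 fell with the block; median 0.31, camera adjusted p = 0.0228; adjusted p = 0.483 with an estimated correlation). The adhesion list did not pass without brain replicate 1 (adjusted p = 0.168) or with the stricter filter (adjusted p = 0.0537). The ITGB2 call ended by limma-voom (adjusted p = 0.0610), with the stricter filter (adjusted p = 0.0615) and among protein-coding genes alone (adjusted p = 0.0588). It also ended by edgeR's bias-adjusted variant (adjusted p = 0.0501), and without brain replicate 1, spleen replicate 1 or spleen replicate 2.

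HMOX1, which degrades haem, fell by 3.09 on the log2 scale (SE 0.54, adjusted p = 0.0367), from 1.81 ± 1.05 CPM in spleen to 0.211 ± 0.00804 in brain. Its call ended by limma-voom (adjusted p = 0.0536), with the stricter filter (adjusted p = 0.0573) and among protein-coding genes alone (adjusted p = 0.0566). It was 1 of 11 oxidative stress genes (2 fell adjusted over the list alone and 2 with the block; median -0.32, camera adjusted p = 0.00711; adjusted p = 0.434 with an estimated correlation). Serine and one-carbon genes had 0 of 11 called, 1 lower with the block, and a median of -0.27 (camera adjusted p = 0.00783; adjusted p = 0.434 with an estimated correlation). Ribosome biogenesis and MYC targets had 0 of 18 called, 1 lower with the block, and a median of -0.24 (camera adjusted p = 0.00439; adjusted p = 0.464 with an estimated correlation), and did not pass without brain replicate 2 (adjusted p = 0.0636). Replication-dependent histones had 0 of 13 called, 2 lower with the block, and a median of -0.27 (camera adjusted p = 0.0444; adjusted p = 0.464 with an estimated correlation), and did not pass after removal of the GC and length trend (adjusted p = 0.437), without brain replicate 2 (adjusted p = 0.0873) or spleen replicate 1 (adjusted p = 0.471), with the stricter filter (adjusted p = 0.301) or after thinning (adjusted p = 0.120). The unfolded protein response did not pass (median -0.19, adjusted p = 0.0561; 2 members lower with the block), but passed lower in brain in 7 settings, among them no filter (adjusted p = 0.0237), limma-voom (adjusted p = 0.0367) and removal of the GC and length trend (adjusted p = 0.0117). Other lists that did not pass, with median and adjusted p, were the amino acid response (-0.16, 0.292), cytosolic ribosomal proteins (0.03, 0.788), heat shock (0.03, 0.743), apoptosis regulators (-0.09, 0.707), p53 targets (0.40, 0.145) and autophagy and lysosome (-0.14, 0.225; without spleen replicate 1, 0.0186). With the block 2 heat shock and 2 p53 members were called higher, 1 of the amino acid response higher, and 1 apoptosis regulator in each direction. Nuclear-retained RNAs did not pass (3 members, median 0.65, adjusted p = 0.120; with the block 0.0354, with 2 members higher; without brain replicate 1, median 0.78 and adjusted p = 0.00761; without spleen replicate 1, median 1.20 and adjusted p = 0.00215), and MALAT1 among them had a log2 fold change of 1.08 ± 0.59 (adjusted p = 0.409; with the block 0.000379). MALAT1 passed without spleen replicate 1 (1.97, adjusted p = 2.59e-07), spleen replicate 2 (0.53, adjusted p = 0.0118) or brain replicate 1 (1.21, adjusted p = 0.0203).

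Some genes of B-cell activation were chosen after the values had been seen, and are therefore no test of that theme. IRF4 and BACH2, transcription factors of the B lineage, rose by 2.22 ± 0.19 and 2.14 ± 0.19, and BCL6, a transcription factor of B cells, by 2.99 ± 0.40 (adjusted p = 0.0155). CD86, a costimulatory ligand, rose by 1.77 ± 0.24 and CD9, a tetraspanin, by 3.92 ± 0.28. Of 23 chromosomes 0 passed as a set, with a smallest adjusted p of 0.328.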
